A study of Homo sapiens with 4 samples.

How the data were processed

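Polyadenylated RNA of THP-1 cells was measured in 4 groups (control, cytarabine, cytarabine then FL-Fc-DM1, and cytarabine then FL-Fc) of 1 library each. Per the labels, the cells were kept with 10% fetal bovine serum, RNA was extracted with Trizol, selected with oligo(dT), fragmented, copied with random primers and sequenced on an Illumina HiSeq2500. Per the submitters' processing notes, fastp 0.18.0, HISAT2, StringTie 1.3.1, DESeq2 and edgeR were named, with no role or order taken from them here. Genome build, annotation release and strandedness are not given in the sources used here. The authors deposited estimated counts of reads per Ensembl gene for each library, with no normalization applied (estimated counts as deposited, written with decimals), and 86.4% to 87.6% of the values in a library, zeros included, were whole numbers. The same deposited table holds FPKM values, which the authors made by dividing by gene length and by the reads assigned to genes. The gene length implied by counts and FPKM was compared across libraries for 3090 genes, and its highest over its lowest value had a median of 1.025 and was above 1.2 for 48 genes.

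Of 20284 genes in the table, 3742 had no count in any library and 112 had no symbol. A symbol carried by several identifiers (469 symbols) was given to 1 identifier by the reference names where possible (462 symbols). In GENCODE release 29, 97.2% of the identifiers were protein coding. Estimated counts were rounded to whole numbers. They were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, and the factors were 1.023, 1.049, 0.961 and 0.969 for control, cytarabine, FL-Fc-DM1 and FL-Fc. CPM are counts scaled to a common library size with these factors, and fold ratios are ratios of CPM. Log2 ratios use a prior count of 2. Further computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

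The libraries were compared in 6 pairs. With 1 library per group no test of a difference between groups was run. The 95% intervals are exact conditional binomial intervals for ratios and exact Poisson intervals for levels. A gene entered the 2-fold counts at a mean of at least 1 CPM over the 2 libraries compared. Where a library had 0 counts, the fold is a bound against a floor of 3 counts in that library. The 33 gene lists and 24 fixed genes came from background knowledge and not from these libraries. A list's members needed a mean of at least 1 CPM over the 4 groups, and a list at least 5 of them. Each list's median was set against 10000 random lists matched on mean expression in 20 bins, and its spread over members came from 2000 bootstrap draws. The overlap of the fusion-protein libraries was set against 100 simulations that drew them and the cytarabine library from their pooled profile, with counting error only. The 6 marker lists were read as levels.

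Named genes had a symbol, were protein coding where a type is given, and had a mean of at least 10 CPM in the libraries compared. They were the 6 with the highest and the 6 with the lowest log2 ratio in each comparison, up to 4 members of each described list with the largest absolute log2 ratio, and the 24 fixed genes. Some genes that this rule names are not reported here. Others were chosen after their values were seen. In the report these are IL7R and COL1A1 and PAX5 as marker levels, and the naming of MMP1 in the senescence list. The genes in the first 2 paragraphs of the other observations were also chosen in this way.

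Alternatives were DESeq2 1.42.0 size factors, total counts with no composition factor, prior counts of 0.5 and 10, no expression filter or one of 10 CPM, the deposited FPKM with a pseudocount of 1, protein-coding genes with a symbol only, 2-fold by the interval bound nearest 1, and list means. Random lists numbered 2000 for these. The steps were tested on simulated pairs of libraries, drawn with Poisson counting error from the pooled profile of each pair, with some genes set apart. These simulated pairs hold no spread between cultures, so the rates below cover counting error only. In the simulated cytarabine and control pair 100.0% of genes set 3-fold apart and 0.07% of unchanged genes came out at least 2-fold apart, and the intervals held the true ratio for 95.4% of genes. In the simulated FL-Fc-DM1 and FL-Fc pair these values were 100.0%, 0.04% and 95.2%. Of 200 lists with no effect, 10 and 12 lay outside the middle 95% of random lists. Tests that need replicates were left out.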

Results

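RNA was measured in THP-1, an established human line of acute monocytic leukaemia cells, in 4 groups of 1 library each. Control cells were cultured for 4 days. Cytarabine cells received 20 µM cytarabine, a nucleoside analogue that blocks DNA synthesis, for 4 days. In the other groups 3 days of cytarabine were followed by 24 hours without it, with either 5 nM FL-Fc-DM1 or 5 nM FL-Fc. The labels give these agents only by code. FL-Fc is taken here as the ligand of the receptor tyrosine kinase FLT3 joined to an antibody Fc part, and DM1 as the maytansinoid payload that binds tubulin. The gene counts summed to 18011718 in the control library, 17393127 in the cytarabine library, 23495641 in the FL-Fc-DM1 library and 21452610 in the FL-Fc library. At these depths 12846 to 13233 genes had at least 10 counts. With 1 library in each group, no difference reported here has a replicate check, and no p-value is given. Each ratio compares 1 library with another, and its 95% interval covers counting error only.

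Among the genes fixed in advance, FLT3 (ENSG00000122025) stood at 85.7 CPM (counts scaled to a common library size) in the control library and 94.7 in the cytarabine library, against 31.4 with FL-Fc-DM1 and 44.2 with FL-Fc. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 22.4 CPM in the control library, 79.4 with cytarabine, 202 with FL-Fc-DM1 and 156 with FL-Fc. MYC went the other way, with 255, 123, 56.1 and 81.8 CPM in the same order. The monocyte receptor CD14 was at 3.04 and 2.63 CPM in the control and cytarabine libraries and at 336 and 250 in the FL-Fc-DM1 and FL-Fc libraries. DUSP6, a phosphatase induced by ERK signalling, was at 24.7 and 23.1 against 356 and 307. The proliferation marker MKI67 was at 154 CPM in the control library, 329 with cytarabine and 346 with FL-Fc, and 1.70 times lower with FL-Fc-DM1 than with FL-Fc. Of the genes that handle cytarabine, DCK, the kinase that activates it, was at 84.7, 142, 72.6 and 93.6 CPM, and SAMHD1, which cleaves its triphosphate, at 712, 648, 612 and 756. CDA, the deaminase that inactivates it, was at 3.91, 5.42, 2.08 and 2.12. ABCB1, a drug efflux pump, had 5, 2, 45 and 26 counts in these libraries, and CISH, a STAT5 target, lay at 10.3, 11.2, 3.45 and 6.40 CPM. CCND1, encoding cyclin D1, had 73, 61, 648 and 396 counts, and the integrin gene ITGAM was at 54.8, 77.3, 94.2 and 157 CPM. The housekeeping genes GAPDH and ACTB spanned 1.42-fold and 1.33-fold from the lowest to the highest library.

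**Figure D1:**
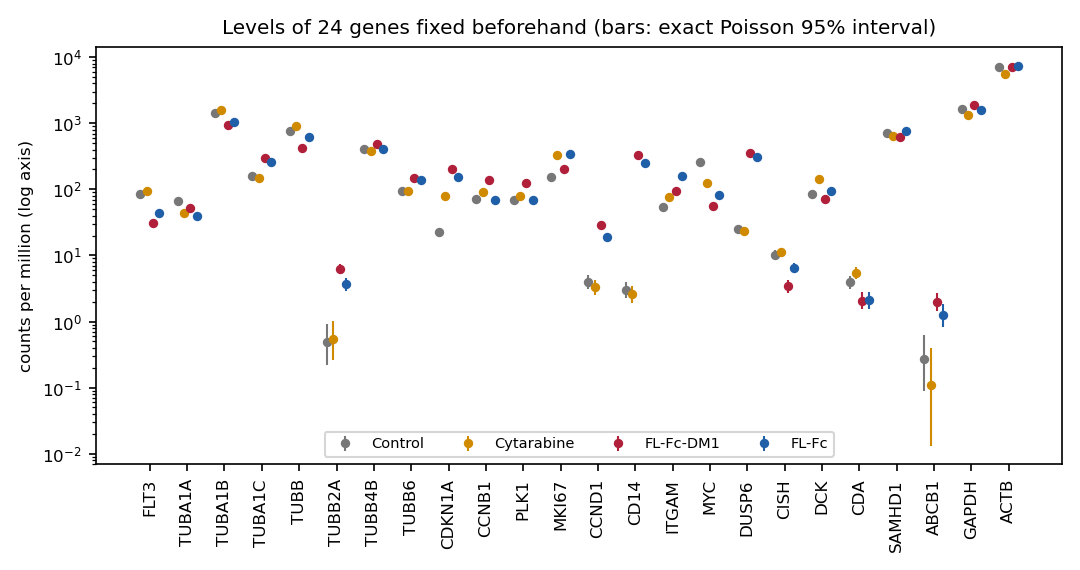
Levels of 24 genes fixed in advance, in CPM on a log axis, for the 4 libraries (1 point per library, bars for the exact Poisson 95% interval, which covers counting error only). CD14 and DUSP6 sit far higher in both fusion-protein libraries (336 and 250, 356 and 307) than in the control (3.04 and 24.7) and cytarabine (2.63 and 23.1) libraries.

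The comparison of cytarabine with control cells asked how THP-1 cells differ after 4 days of the drug. Genes of DNA replication, mitosis and DNA repair were higher in the cytarabine library, and genes of ribosomal proteins were lower. The 6 named genes with the highest ratios were STC2, a secreted glycoprotein gene of the stress response (3.81-fold, 95% interval 3.36 to 4.32), FAM111B (3.76-fold, 3.15 to 4.51), the cyclin E2 gene CCNE2 (3.66-fold, 3.38 to 3.98), the acute-phase gene ORM1 (3.64-fold, 3.46 to 3.84), CDKN1A (3.54-fold, 3.17 to 3.96) and the chaperone gene CLGN (3.36-fold, 2.77 to 4.10). Among the lowest were the cytokine gene TNF, at 2.46 times lower (2.02 to 3.00), and B3GNT7, LDLRAD4, MOSPD3 and COL23A1, at 2.36, 2.36, 2.21 and 2.18 times lower. In all, 315 genes were at least 2-fold higher and 85 at least 2-fold lower, together 3.2% of 12313 genes.

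All 52 genes of the DNA replication and S phase list had ratios above 1 in cytarabine against control, 12 of them by at least 2-fold, with a median log2 ratio of 0.78. The middle 95% of 10000 random lists matched on mean expression, given throughout as a description of these libraries, ran from -0.10 to 0.09. RRM2, a subunit of ribonucleotide reductase, was 2.86-fold higher (2.74 to 2.98), E2F2 2.58-fold, and CCNE1 was at 54.9 against 21.9 CPM. All 53 genes of the mitosis and G2/M list were also above 1, with a median of 0.91 and 21 genes at least 2-fold higher, among them the kinetochore genes NDC80 (2.59-fold) and SPC25 (2.41-fold), the spindle gene DLGAP5 (2.46-fold) and SGO1, which protects centromere cohesion (2.38-fold). CCNB1 and PLK1 were 1.27-fold (1.18 to 1.37) and 1.13-fold (1.05 to 1.22) higher. The 34 genes of DNA damage response and repair had a median of 0.73, with 12 at least 2-fold higher and none lower, such as RBBP8 (2.72-fold), BRIP1 (2.64-fold), BRCA2 (2.63-fold) and EXO1 (2.36-fold). Among 31 genes of the unfolded protein and integrated stress response 28 were above 1 and 4 at least 2-fold higher, with a median of 0.36, and DDIT4, DDIT3 and TRIB3 were 2.28-fold, 2.10-fold and 1.96-fold higher. The p53 target list had a median of 0.25 with 2 of 28 genes at least 2-fold higher. Among its named genes were CDKN1A, SESN2 (1.93-fold), GADD45A (1.87-fold) and MDM2 (1.61-fold). The apoptosis inducer gene PMAIP1 was 1.96-fold higher (1.77 to 2.19), in a BCL2 family list whose median was 0.05.

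All 77 cytosolic ribosomal protein genes had ratios below 1 in the cytarabine library, with a median log2 of -0.43 and none at least 2-fold lower. RPS28 was 1.64 times lower (1.55 to 1.74) and RPL13 1.62 times lower (1.58 to 1.66). The ribosome biogenesis and MYC target list had a median of -0.37 and held MYC itself, at 2.08 times lower (1.97 to 2.18). Nuclear-encoded genes of oxidative phosphorylation had a median of -0.23, with 36 of 38 below 1, and cholesterol synthesis genes one of -0.22. Interferon-stimulated genes (median 0.17), the NF-kB and inflammatory cytokine list (0.00), monocyte and macrophage markers (0.09) and genes of neutrophil granules (-0.10) stood near 0, each with at most 2 genes 2-fold apart in either direction. Only the first of these 4 medians lay outside the middle 95% of its random lists, and it lay inside with the deposited FPKM (0.11). The replication-dependent histone list had a median of -1.18 over the 10 members that passed the expression floor, and -0.19 with no floor. The messages of these genes mostly lack the poly(A) tail on which the libraries were selected, so their levels are uncertain. The number of genes at least 2-fold apart, Cytarabine against Control, was 400 in all, and 133 where the counting interval had to exclude 2-fold, 163 at a mean of at least 10 CPM, 169 with FPKM and 1354 with no floor.

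**Figure D2:**
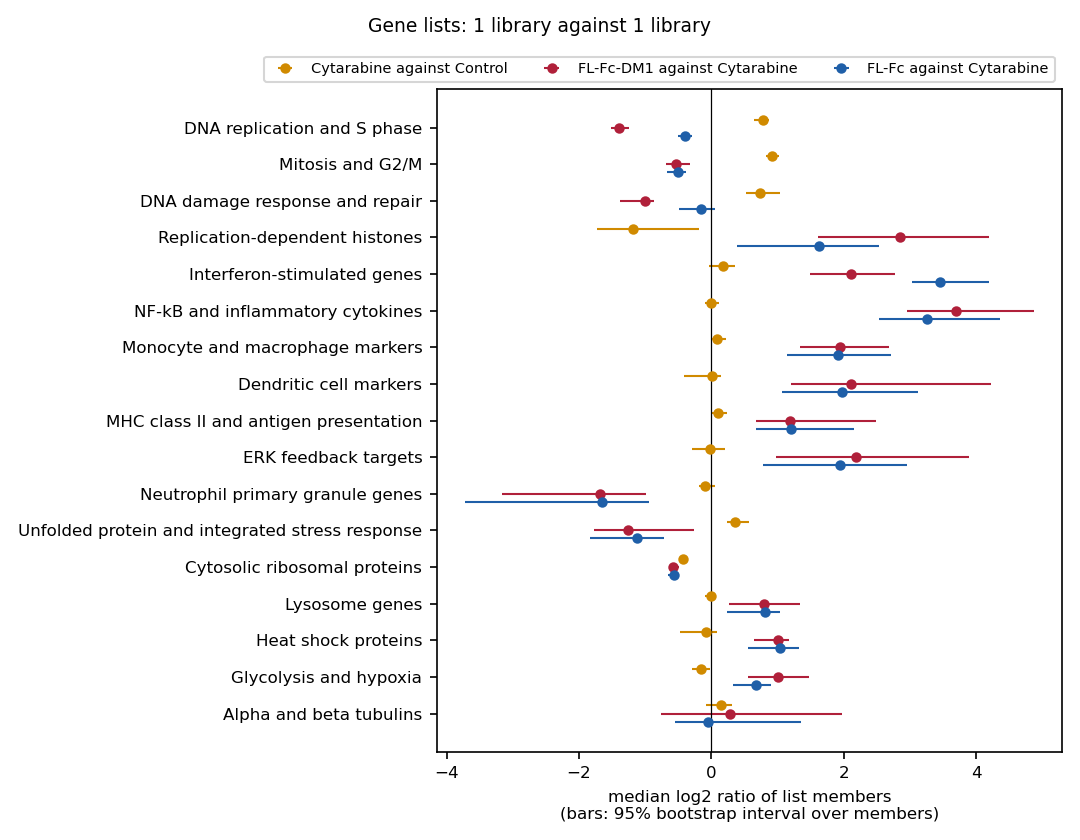
Median log2 ratio of the members of 17 gene lists (horizontal axis) in 3 comparisons of 1 library with another, with bars for the 95% bootstrap interval over list members. NF-kB and interferon-stimulated genes stand near 0 for cytarabine against control (0.00 and 0.17) and far above 0 for both fusion-protein libraries against cytarabine (3.70 and 2.11 with FL-Fc-DM1, 3.26 and 3.46 with FL-Fc).

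FL-Fc-DM1 and FL-Fc were given at the same concentration, for the same time and after the same pretreatment. By the labels, these treatments differed by the DM1 payload. The pair of libraries may also hold a difference between single cultures, which could not be separated from the payload without replicates. Interferon-stimulated genes, DNA replication genes and DNA repair genes were lower with FL-Fc-DM1, while growth factor, chemokine and immediate-early genes led the higher side. IGFBP5 (ENSG00000115461), a binding protein of insulin-like growth factors, was at 876 CPM with FL-Fc-DM1 and 80.2 with FL-Fc, a ratio of 10.9 (95% interval 10.4 to 11.5). CRLF2, a subunit of the thymic stromal lymphopoietin receptor, was 9.92-fold higher (58.2 against 5.87 CPM), the chemokine gene CCL24 5.84-fold (5.43 to 6.30), ADPRHL1 5.43-fold and NT5E, the ecto-nucleotidase CD73, 4.74-fold. At the other end CXCL10, an interferon-induced chemokine gene, was 10.7 times lower (7.99 to 14.5), CMPK2 7.08 times lower (6.41 to 7.83), IFIT2 6.70, FAM111B 6.18, CCL8 6.07 and IFI44L 5.84 times lower. At least 2-fold apart were 237 genes on the higher side and 334 on the lower side, 4.6% of 12431.

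Of 45 interferon-stimulated genes, 44 had ratios below 1 with FL-Fc-DM1 against FL-Fc and 30 were at least 2-fold lower, with a median log2 ratio of -1.28 (random lists -0.11 to 0.09). All 52 genes of DNA replication and S phase were below 1, 24 of them by at least 2-fold, with a median of -0.97. CCNE2 had a log2 ratio of -1.92, RRM2 was 3.30 times lower (3.14 to 3.47), the replication helicase gene CDC45 3.10 times and CLSPN, a mediator of the replication checkpoint, 2.84 times lower. In the DNA repair list 32 of 34 genes were below 1 and 13 at least 2-fold lower, with a median of -0.92, including BRIP1 (3.65 times lower), BRCA2 (3.11), EXO1 (3.07) and RBBP8 (2.89). The mitosis and G2/M list differed from these. None of its 53 genes was 2-fold apart, 30 were above and 23 below 1, and its median was 0.25 with a 95% bootstrap interval over members of -0.15 to 0.33. Its largest ratios went both ways, with CCNB1 at 1.99-fold (1.87 to 2.12), KIF20A at 1.94-fold and PLK1 at 1.81-fold higher, against KIF20B and SPC25, each 1.92 times lower. Genes of cytarabine transport and nucleotide metabolism had a median of -0.28. The named members of this list went both ways, with NT5E 4.74-fold higher, TYMS, encoding thymidylate synthase, 2.68 times lower and DHODH 2.12 times lower. Ribosome biogenesis genes had a median of -0.34, with 27 of 30 below 1.

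The NF-kB and inflammatory cytokine list had a median of 0.32 in the same comparison, with 4 of 39 genes at least 2-fold higher and 2 lower. The chemokine gene CCL22 was 4.30-fold higher (4.09 to 4.53), IER3 2.55-fold and the interleukin gene IL1B 1.83-fold, whereas CCL2 was 2.21 times lower (2.14 to 2.28). Immediate-early and AP-1 genes had a median of 0.49 with 6 of 26 at least 2-fold higher, such as MAFF (3.03-fold), and JUN was 1.59-fold higher. ERK feedback targets had a median of 0.27, with PHLDA1 2.39-fold and DUSP4 2.03-fold higher. Genes of glycolysis and hypoxia had a median of 0.31, with 25 of 26 above 1 and VEGFA 2.21-fold higher (2.10 to 2.33). Of the cell adhesion and cytoskeleton genes, RHOB was 3.71-fold higher (3.21 to 4.30) and THBS1, encoding thrombospondin, 2.81-fold, and the list's median was 0.18. In the list of MHC class II and antigen presentation (median 0.17), CIITA, the class II transactivator, was 3.34-fold higher (3.03 to 3.68). Monocyte and macrophage markers had a median of 0.11 and differed in direction, with TREM1, CD86 and SPP1 2.52-fold, 2.12-fold and 2.08-fold higher and LYZ, encoding lysozyme, 2.11 times lower. KIT was 2.61-fold higher and FLT3 1.41 times lower (1.28 to 1.56). Of the p53 targets (median 0.16) TP53INP1 was at 23.2 against 9.28 CPM, and of the apoptosis genes (median 0.07) the death ligand gene TNFSF10 was 2.45 times lower. Cytosolic ribosomal proteins (0.01), oxidative phosphorylation (0.01), heat shock proteins (-0.07) and stress response genes (-0.04) had medians near 0.

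The genes for alpha and beta tubulin, whose protein is the target of DM1, went both ways. TUBB was 1.45 times lower with FL-Fc-DM1 than with FL-Fc (1.41 to 1.49), TUBA4A 1.18 times lower (1.07 to 1.31) and TUBA1B 1.12 times lower (1.10 to 1.15), while TUBA1A was 1.32-fold higher (1.21 to 1.45), TUBA1C 1.15-fold, TUBB6 1.07-fold, TUBB4B by 487 to 405 CPM and the low-level TUBB2A 1.67-fold (1.26 to 2.24). The list median was 0.24, outside the middle 95% of random lists, but inside it by the list mean (0.23). Other tubulins and microtubule regulators had a median of -0.11, with the microtubule-destabilising gene STMN1 1.42 times lower. Tubulin and histone genes share near-identical copies, so their counts are uncertain. Histone genes above the floor had a median of 1.25, with H2AC6 3.60-fold and H2BC21 2.43-fold higher, and 0.53 with no floor. Dendritic cell markers had a median of 0.56, led by LAMP3 (2.97-fold), but -0.10 at a floor of 10 CPM. Neutrophil granule genes had a median of 0.20 and a mean of -0.29. The number of genes at least 2-fold apart, FL-Fc-DM1 against FL-Fc, was 571 in all, and 278 where the interval had to exclude 2-fold, 262 at a mean of at least 10 CPM, 257 with FPKM and 1267 with no floor.

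**Figure D3:**
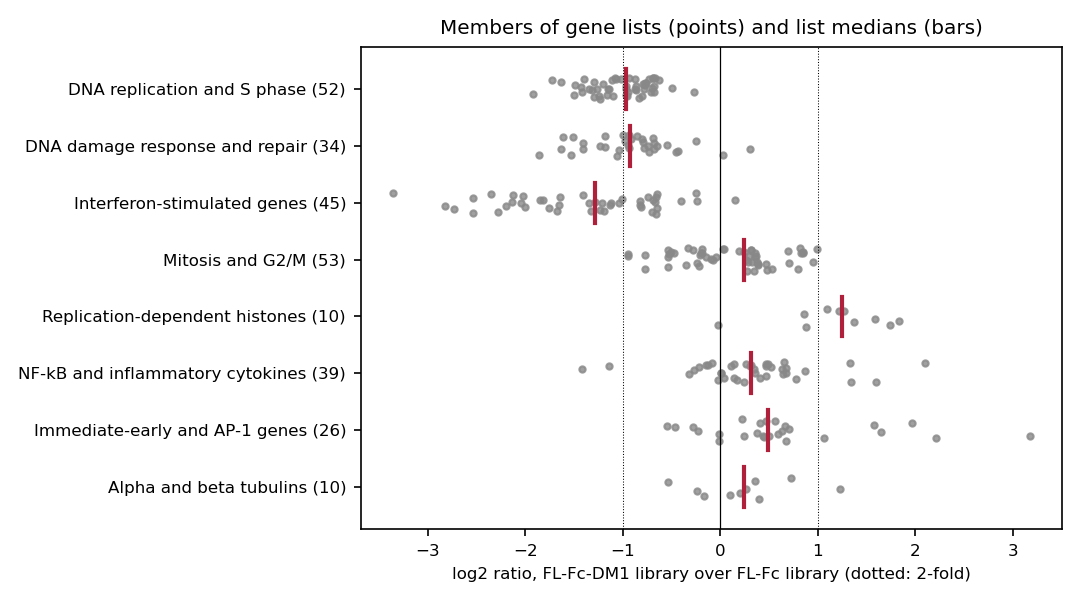
Log2 ratio of the FL-Fc-DM1 library over the FL-Fc library for each member of 8 gene lists (grey points, number of members in parentheses) with the list median (red bars), and dotted lines at 2-fold. All 52 S phase genes lie left of 0 (median -0.97), whereas the mitosis genes lie on both sides (median 0.25).

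The fusion-protein libraries were next set against the cytarabine library. Cytarabine had been taken away from the cells of both, so these ratios hold its removal together with the added protein. Inflammatory cytokine, interferon-stimulated, macrophage and antigen presentation genes had higher medians in both fusion-protein libraries, and genes of neutrophil granules, the unfolded protein and integrated stress response and DNA replication had lower ones. With FL-Fc-DM1, 1647 genes were at least 2-fold higher and 1536 lower, 25.4% of 12543, and with FL-Fc 1397 were higher and 993 lower, 19.1% of 12505. At a mean of at least 10 CPM, the total of genes at least 2-fold apart, FL-Fc-DM1 against Cytarabine, went from 3183 to 1947, and that of genes at least 2-fold apart, FL-Fc against Cytarabine, from 2390 to 1372 (3600 with no floor).

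The gelatinase gene MMP9 (ENSG00000100985), at 2.25 CPM in the cytarabine library, was 1253-fold higher with FL-Fc-DM1 (95% interval 924 to 1747) and 1027-fold higher with FL-Fc (757 to 1432). IGFBP3 was 648-fold (468 to 925) and 352-fold (254 to 503) higher, and IGFBP5 3997-fold (1561 to 14671) and 366-fold (143 to 1345), from 4 counts in the cytarabine library. The chemokine gene CXCL13 had no count with cytarabine and was at least 574-fold and 581-fold higher against a floor of 3 counts in that library, while its counting intervals began at 466 and 472. CXCL8, encoding interleukin 8, was 314-fold higher and the haem oxygenase gene HMOX1 345-fold higher with FL-Fc-DM1. The interleukin 7 receptor gene IL7R was 296-fold higher with FL-Fc (179 to 529), and the collagenase gene MMP8 at least 184-fold against that floor, with an interval that began at 149. MS4A3, a marker of granulocyte and monocyte precursors, was 566 times lower with FL-Fc-DM1 (242 to 1746) and 47.4 times lower with FL-Fc (36.3 to 63.1). SERPINB10 was 282 and 55.7 times lower, CEACAM6 52.1 and 40.8 times lower, and SERPINB2 109 times lower with FL-Fc-DM1 (60.6 to 219). SLC6A9, a glycine transporter gene, was 124 times lower with FL-Fc-DM1 and 458 times lower with FL-Fc (81.7 to 18131, from 1 count). PPP1R27 was 63.6 times lower with FL-Fc-DM1, and INHBE, an inhibin subunit gene, 132 times lower with FL-Fc.

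Of 39 NF-kB and inflammatory cytokine genes, 36 were at least 2-fold higher than with cytarabine in each fusion-protein library, with median log2 ratios of 3.70 with FL-Fc-DM1 and 3.26 with FL-Fc. IL1B was 216-fold higher with FL-Fc-DM1 (156 to 309), and CCL2 172-fold (132 to 228) and CXCL8 196-fold (128 to 316) with FL-Fc. Interferon-stimulated genes were at least 2-fold higher for 37 of 45 members with FL-Fc-DM1, with a median of 2.11, and for all 45 with FL-Fc, with a median of 3.46. IFI44 was 40.9-fold (24.6 to 73.4) and 131-fold (79.1 to 234) higher, ISG15 16.5-fold with FL-Fc-DM1, and IFIT1 142-fold (77.1 to 297) with FL-Fc. Monocyte and macrophage markers had medians of 1.95 and 1.92, with 31 and 30 of 43 genes at least 2-fold higher. CD14 was 128-fold (96.2 to 173) and 94.9-fold (71.5 to 129) higher, the costimulatory ligand gene CD86 115-fold and SPP1, encoding osteopontin, 88.9-fold with FL-Fc-DM1, and the proteoglycan gene VCAN 74.8-fold with FL-Fc. The macrophage growth factor receptor gene CSF1R was 8.97-fold and 6.81-fold higher. MHC class II and antigen presentation genes had median ratios of 2.28-fold and 2.29-fold, and 12 and 13 of 23 were at least 2-fold higher, with HLA-DRA 37.3-fold and 30.8-fold higher, although HLA genes share sequence with close relatives and are uncertain. Dendritic cell markers had medians of 2.11 and 1.98, or 1.15 and 0.98 with FPKM, and LAMP3 was 250-fold and 84.2-fold higher. ERK feedback targets had medians of 2.18 and 1.94, or 0.87 and 1.00 with FPKM. STAT5 targets had medians of 1.12 and 0.90, with SOCS3 36.6-fold and 18.9-fold higher. The STAT5 targets CISH and MYC went the other way. CISH was at 3.45 and 6.40 CPM against 11.2 with cytarabine, and MYC at 56.1 and 81.8 against 123. Immediate-early genes had medians of 1.28 and 0.85.

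Lysosome genes had medians of 0.80 and 0.81, with 14 of 31 at least 2-fold higher in each library, led among the cathepsins by CTSD at 6.43-fold (6.28 to 6.59) and 6.52-fold (6.37 to 6.69). Heat shock protein genes had medians of 1.01 and 1.03, with HSPH1 3.70-fold and 4.19-fold higher. Glycolysis and hypoxia genes had medians of 1.00 and 0.67, with the hexokinase gene HK2 5.27-fold and 5.20-fold and the pyruvate kinase gene PKM 4.84-fold and 4.02-fold higher. ICAM1, an adhesion receptor for leukocytes, was 98.2-fold and 74.1-fold higher, in an adhesion list with medians of 0.50 and 0.37 and means of 1.02 and 0.77. The efflux pump list had medians of 0.88 and 0.76 and was led by ABCC3 (27.3-fold and 23.3-fold), but its median with FPKM was 0.20 and 0.30. Genes of neutrophil primary granules had medians of -1.69 and -1.66, with 9 of 13 at least 2-fold lower in each library, among them the protease genes CTSG (17.4 times lower with FL-Fc, and 14.4 to 15.8 times lower by its interval with FL-Fc-DM1) and PRTN3 (6.95 and 8.14 times lower). The unfolded protein and integrated stress response list had medians of -1.26 and -1.13, with 18 and 17 of 31 genes at least 2-fold lower. Among its named genes, the asparagine synthetase gene ASNS was 26.2 and 24.0 times lower, the serine synthesis gene PSAT1 26.1 and 16.5 times lower and the glutathione-degrading CHAC1 20.2 and 19.7 times lower. Cytosolic ribosomal proteins had medians of -0.58 and -0.57, with 74 and 76 of 77 genes below 1. Of the targets of HOXA and KMT2A fusions, MYB was 6.41 and 3.17 times lower and BCL2, an apoptosis inhibitor, 5.68 and 4.38 times lower, and the list medians were -0.37, inside the middle 95% of random lists, and -0.33, outside it. The senescence list had medians of -0.52 and -0.30 and means of 0.87 and 0.67, with IGFBP3, the matrix protease gene MMP1 and CCND1 furthest above 0.

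S phase genes had a median of -1.39 with FL-Fc-DM1 against cytarabine, with 45 of 52 at least 2-fold lower, and of -0.40 with FL-Fc, with 2 of 52. The transcription factor gene E2F8 was 5.85 and 2.07 times lower. Of 34 DNA repair genes 16 were at least 2-fold lower with FL-Fc-DM1 and none with FL-Fc, where the median was -0.16. Mitosis and G2/M genes had medians of -0.53 and -0.51. CDC20, the activator of the anaphase-promoting complex, was 2.24-fold higher than cytarabine with FL-Fc-DM1 (2.18 to 2.31). CDC25C, a phosphatase of mitotic entry, was 3.25 times lower than cytarabine with FL-Fc. These ratios do not set the fusion-protein libraries apart, since no gene of this list was 2-fold apart between FL-Fc-DM1 and FL-Fc. Histone genes above the floor had medians of 2.85 and 1.63, or 0.92 and 0.57 with no floor. Mitochondrially encoded genes (-0.10 and -0.09), oxidative phosphorylation (-0.02 and 0.03), p53 targets (0.07 and -0.07), alpha and beta tubulins (0.28 and -0.05), the FLT3 and growth factor receptor list (0.09 and -0.05) and the 17-gene leukaemia stem cell score list (0.52 and 0.40) had medians inside the middle 95% of their random lists.

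The fusion-protein libraries shared 1206 genes at least 2-fold higher than cytarabine, out of 1563 with FL-Fc-DM1 (77.2%) and 1361 with FL-Fc (88.6%). They shared 823 genes at least 2-fold lower, out of 1533 (53.7%) and 988 (83.3%). These numbers cover the 12410 genes that passed the expression floor in both comparisons. Independent lists of these sizes would share 171.4 and 122.0 genes. In simulations that drew the cytarabine and both fusion-protein libraries from their pooled profile, 1.05 and 0.12 genes were shared on average. These simulations hold counting error only and no spread between cultures. Both comparisons use the same cytarabine library, so part of the excess over these values may come from it, and with 1 library it could not be split. Set against the control library instead, which both comparisons again share, 1227 genes were shared on the higher side and 790 on the lower side. Against the control library, 1600 genes were at least 2-fold higher and 1225 lower with FL-Fc-DM1, and 1519 higher and 986 lower with FL-Fc, 2825 and 2505 in all. At a mean of at least 10 CPM these totals of genes at least 2-fold apart, FL-Fc-DM1 against Control and genes at least 2-fold apart, FL-Fc against Control, were 1668 and 1493. MMP9 was 1571-fold and 1288-fold higher than in the control library and MS4A3 571 and 47.8 times lower. NF-kB genes had medians of 3.67 and 3.18, interferon-stimulated genes 2.37 and 3.77, and monocyte and macrophage markers 1.81 and 1.99. S phase genes had a median of -0.58 with FL-Fc-DM1 and 0.40 with FL-Fc, whereas mitosis genes had 0.42 and 0.32. Cytosolic ribosomal proteins had medians of -0.97 and -1.07, with 37 and 45 of 77 genes at least 2-fold lower than in the control library.

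Markers of cell types that a pure THP-1 culture should lack were low in the fusion-protein libraries, in which the inflammatory and macrophage genes were high. The highest median of the 6 marker lists there was 0.753 CPM, for megakaryocyte genes. The T cell list had medians of 0.0443 and 0 CPM with FL-Fc-DM1 and FL-Fc, although it holds IL7R, at 239 and 243. Fibroblast markers had medians of 0.531 and 0.481, against 0 in the control library and 0.0274 with cytarabine, with COL1A1 at 4.78 and 3.70 CPM. The B cell list had medians of 0.465 and 0.385, with PAX5 at 7.48 and 16.2 CPM, against 5.16 in the control library and 9.53 with cytarabine. Epithelial markers had medians of 0.0886 and 0.144, and erythroid markers of 0 in all 4 libraries.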

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

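Gene lists, the fixed genes, comparisons and the thresholds for ratios and lists were chosen before the data were examined. The tests of mixed-in cells, of a return to the untreated state, of a weaker response as a whole and of a smaller share of cycling cells were chosen only after the result was seen. The bounds of these tests were set at that time too.

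Of 344 named genes, 10 lay on opposite sides of the cytarabine library in the FL-Fc-DM1 and FL-Fc libraries, by counting intervals under 3 scalings. Some of the named genes were picked for large ratios in these same comparisons, so this is no share of all genes. The mitotic genes CCNB1, KIF20A and PLK1, which act in entry into and passage through mitosis, were higher than cytarabine with FL-Fc-DM1 (1.53-fold, 1.28-fold and 1.59-fold) and lower with FL-Fc (ratios of 0.768, 0.662 and 0.876). Their log2 ratios of FL-Fc-DM1 over FL-Fc were 0.99, 0.95 and 0.85. KLF10, a TGF-beta-induced transcription factor gene, went the same way, with 0.68. The other 6 genes were lower than cytarabine with FL-Fc-DM1 and higher with FL-Fc. FAM111B had the largest difference (-2.62, with ratios of 0.343 and 2.12), followed by the pyrimidine synthesis gene DHODH (-1.07), the histone demethylase gene JMJD1C (-0.83), CTPS1, another gene of pyrimidine synthesis (-0.69), the ribosome biogenesis gene NOP58 (-0.52) and SAMHD1 (-0.31). In the FL-Fc library CCNB1, PLK1 and DHODH stood at 70.0, 68.3 and 14.4 CPM, near their control levels of 71.7, 69.0 and 13.8. The other genes lay further from control by ratio, FAM111B the most (68.4 against 8.58 CPM). With 1 library per group the differences between the groups were not tested.

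The NF-kB and inflammatory cytokine list was higher in both fusion-protein libraries than with cytarabine (medians of 3.70 and 3.26). Correction for GC content and transcript length left medians of 3.83 and 3.09, which argues against these trends as the cause. Mixed-in lymphoid, erythroid, megakaryocytic, epithelial or fibroblast cells are argued against by marker lists whose highest median was 0.753 CPM. No marker list covered myeloid cells other than THP-1, so their admixture was not tested. A return to the untreated state after cytarabine was taken away would not give medians of at least 3.18 over the control library. However, the cytarabine and control libraries hardly differed in this list, so that outcome already followed from the medians over cytarabine. It adds no separate evidence. The added protein and cytarabine removal stay open, since no library had the removal alone, and so does an exchange of medium, which the labels do not state, all untested.

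Interferon-stimulated genes had a median of -1.28 in FL-Fc-DM1 against FL-Fc. The median after correction for GC content and length was -1.24, which argues against those trends as the cause. The NF-kB list was not lower in the same comparison, with a median of 0.32 and a bootstrap interval above 0. No library had the removal of cytarabine alone, so whether this list reports the response to the protein is unknown. It therefore cannot decide on a weaker response to the fusion protein as a whole, which stays open. The DM1 payload, as a hypothesis, and a difference between single cultures also stay open, and neither was tested.

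S phase genes had a median of -0.97 in FL-Fc-DM1 against FL-Fc, and -0.99 after correction for GC content and length, which argues against those trends. A smaller share of cycling cells alone would lower the mitosis list too, but its median was 0.25 with a bootstrap interval of -0.15 to 0.33. Its members went both ways, with 23 of 53 below 1, and MKI67 was 1.70 times lower (1.64 to 1.77), so a smaller share of cycling cells as part of the difference is not excluded. A first bound, the whole interval above 0, decided nothing, and the bound used instead, the interval above 0.5 of the S phase median, was set after that. Fewer cycling cells together with more of them in mitosis could give both values and stays open beside the DM1 payload and a difference between single cultures, all untested.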

How the results depend on the processing

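Comparing the sharing of 2-fold genes across settings was chosen only after the result was seen. No paired analysis was possible because each group holds 1 library. Of 54 counts of 2-fold genes under alternatives, 41 stayed within 1.5 times the main count and 13 did not. For genes at least 2-fold apart, Cytarabine against Control (400), the count was 169 with FPKM, 1354 with no filter, 163 at a mean of at least 10 CPM and 133 by the interval bound. For genes at least 2-fold apart, FL-Fc-DM1 against FL-Fc (571), it was 257, 1267, 262 and 278. At 10 CPM, genes at least 2-fold apart, FL-Fc-DM1 against Cytarabine (3183) numbered 1947, genes at least 2-fold apart, FL-Fc against Cytarabine (2390) 1372 (3600 with no filter), genes at least 2-fold apart, FL-Fc-DM1 against Control (2825) 1668 and genes at least 2-fold apart, FL-Fc against Control (2505) 1493. The stricter filter and the interval bound admit fewer genes by construction. The pseudocount of 1 added to FPKM shrinks ratios of low-level genes by construction, and whether it accounts for the whole drop was not tested. Of 1374 list medians 1336 lay within the bootstrap interval over members, 35 moved outside it and 3 of lists outside the random range reversed, and of 891 outside the random lists 34 no longer were. Reversed were dendritic cell markers (list Dendritic cell markers, FL-Fc-DM1 against FL-Fc) at -0.10 with the 10 CPM filter, from 0.56, granule genes (list Neutrophil primary granule genes, FL-Fc-DM1 against FL-Fc) at -0.29 by the mean, from 0.20, and the senescence list (list Senescence and cell-cycle inhibitors, FL-Fc-DM1 against Cytarabine) at 0.87 by the mean, from -0.52. For these the cause was not tested. Of 4410 values of named genes 3630 stayed within their counting interval and 780 moved, 510 of them with FPKM, and none of those at least 2-fold apart reversed. With total counts and no composition factor the median log2 ratio of all genes in FL-Fc-DM1 against Cytarabine was -0.129, against -0.003 with TMM. The pseudocount of 0.1 and all alternatives that need replicates were not run. Depth limits genes with few counts, such as ABCB1 with 2 counts with cytarabine.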

Other observations

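The genes in the first 2 paragraphs and the test of tubulin messages were chosen only after the result was seen. Several genes of iron and metal handling, which were not tested as a list, are given as single values. FTH1, the ferritin heavy chain, was at 600 and 624 CPM in the control and cytarabine libraries and 20.8-fold (20.4 to 21.2) and 14.2-fold (13.9 to 14.4) higher than cytarabine with FL-Fc-DM1 and FL-Fc, and the light chain FTL 3.22-fold and 2.99-fold. HMOX1, which releases iron from haem, was 345-fold and 216-fold higher, and the iron exporter SLC40A1 5.31 and 3.57 times lower. The transferrin receptor gene TFRC was 1.78-fold and 2.11-fold higher. The metallothionein genes MT1X and MT2A, whose proteins bind zinc and copper, were 19.9-fold and 13.1-fold higher with FL-Fc-DM1 and MT1X 12.1-fold higher with FL-Fc. Ferritin and metallothionein genes have close copies and are uncertain.

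Receptor genes of the cytokines interleukin 7 and thymic stromal lymphopoietin were also high. IL7R was 291-fold (176 to 520) and 296-fold (179 to 529) higher than cytarabine, and CRLF2 66.4-fold (40.7 to 117) and 6.69-fold (3.96 to 12.1). IL2RG stood at 15.7 and 10.6 CPM against 2.41 with cytarabine, and TSLP, the ligand, at 0.310 and 0.337 against 1.48. The T cell gene CD3E had 0 counts in all libraries. The interferon regulatory factor gene IRF7 was 3.99-fold and 7.05-fold higher than cytarabine. The summed counts of 21 interferon genes were 1, 0, 2 and 4 in the control, cytarabine, FL-Fc-DM1 and FL-Fc libraries.

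A tubulin-binding drug that frees tubulin dimers may lower tubulin messages, a known autoregulation. Summed CPM of 10 alpha and beta tubulin genes were 2386 with FL-Fc-DM1 and 2546 with FL-Fc, a ratio of 0.937 (0.926 to 0.949). The sum was thus slightly lower with FL-Fc-DM1, though above the bound of 0.9 set against a general loss of these messages. This bound was set after the result was seen. TUBB alone was 1.45 times lower, and autoregulation of single genes stays open and was not tested.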
